A study of Mus musculus with 2 samples.

How the data were processed

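Messenger RNA of the proximal small intestine was measured on 2 Affymetrix expression arrays, 1 for wild-type (WT) C57BL/6 mice and 1 for mice of the same background with a germline deletion of Cd36 (CD36KO). Per the labels' protocols, RNA of 3 chow-fed animals was extracted with TRIzol and pooled per genotype, and biotinylated cRNA was made from 100 ng of total RNA. Each genotype is therefore a single measurement of a pool, n = 1 per group. The spread between animals was lost in the pooling and the spread between arrays was not measured.

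The values were deposited by the authors as one table of 45101 probe sets on a log2 scale. The log base follows from the values, which reach 14.2. Read as natural logarithms they would reach 1.46e+06, beyond the 65535 of a 16-bit scanner. The summarization and normalization methods are not given in the sources used here. The medians of the WT and CD36KO columns were 4.38 and 4.38, and their quartiles were close without being identical. The table gives neither detection calls nor background, so a low value cannot be told from no signal.

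Probe sets were named from the annotation of the array: 34958 carried 1 gene symbol, 932 carried several and were not named, and 9211 were unnamed here. The identifiers of 34754 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. This table served only for names and for the order of genes along the chromosome. Members of the fixed gene lists were matched by symbol or, where a symbol was no longer current, by a synonym in that table. For each of the 18194 genes the probe set with the highest mean over the arrays was used. A gene was kept where the higher of its values was at or above 4.51, the median of that quantity over all probe sets, which left 11981 genes. Several gene families on the array (serum amyloids, digestive proteases, carboxylesterases, immunoglobulin segments) have near-identical members whose probe sets may share signal.

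What was computed is the CD36KO minus WT difference of the deposited log2 values, with no further normalization. With 1 array per genotype no test was run, no p-value is given, and a difference cannot be set against replicate error. Counts of genes at 2-fold or 1.5-fold describe these arrays. For gene lists, the median difference of the members above the expression filter was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Genes of a list are co-regulated while randomly drawn genes are not, so this percentile is a description of the arrays and not a test of genotype. The range quoted for random lists holds their middle 95%.

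Before the data were examined, 41 gene lists, the value rule, the alternatives and the rule for named genes were fixed. Named were Cd36 with all probe sets, the 15 genes with the largest difference in each direction (leaving out predicted genes, Riken clones and LOC symbols), up to 4 members with the largest absolute difference in each list, and 8 in the lists that answer the title of the series (extracellular matrix, made by joining 3 of the lists, and neutrophil markers). Other members are named as examples chosen after their values were seen. Lists of further distal, further proximal and further pancreas genes, of bile acid receptor targets and of type 2 immune genes, and reduced forms of the fixed lists, were written later. Without distal, serum amyloid and colon goblet genes the Paneth list had a median of 1.14, without distal genes the goblet list had one of 0.82, and without pancreas genes the fat absorption list had one of -0.21. The alternatives were centring on the median, quantile normalization, removal of a lowess trend (fraction 0.3), the mean over a gene's probe sets, the probe set with the smallest absolute difference per gene, no filter, a filter at the 75th percentile, and thresholds of 1.5-fold and 3-fold. Leaving out a replicate was not possible with 1 array per genotype.

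Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The procedure was tested on simulated data made from the levels of these arrays with a noise SD of 0.257. All 200 genes shifted 4-fold were recovered past 2-fold, and 0 unshifted genes passed it, among 12009 genes with the shifted ones included. A list of 25 genes shifted by 0.3 reached percentile 100, and 5 of 100 unshifted lists fell outside the middle 95%. This noise was taken from these arrays and holds no variation between animals. It had the same SD at every level, while the measured differences above the filter had an SD of 0.41. The simulated count of 0 is therefore no error rate for these arrays.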

Results

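The series compared gene expression in the proximal section of the intestine between WT mice and mice lacking CD36, a membrane receptor for long-chain fatty acids, oxidized lipoproteins and thrombospondin. Its title names the extracellular matrix of the intestine and neutrophils. The data comprised 2 arrays, a pool of 3 WT animals and a pool of 3 CD36KO animals. The deposited log2 values correlated across all probe sets with Pearson's r = 0.988 (probe sets are not independent replicates). Their median was 4.38 on both arrays. There was no replicate array, so none of the differences below could be compared with variation between animals or arrays, and the number of arrays limits the precision of every value.

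The RNA differed in 5' to 3' coverage between the pools. The 3' minus 5' difference of the beta-actin control probe sets was 2.28 (log2) in WT and 1.34 in CD36KO, and that of GAPDH was 1.28 in WT and 0.71 in CD36KO. All 18 hybridization control probe sets were lower on the CD36KO array, by a median difference of -0.28, and 23 of 24 poly-A control probe sets were, by a median of -0.57. The genes above the filter had a median difference of -0.0059. Xist, the RNA of the inactive X chromosome, was at 9.70 in WT and 9.63 in CD36KO, with another probe set at a difference of -0.93. The Y-linked genes Eif2s3y, Kdm5d and Uty were all at 3.31 or below in both pools, under the expression filter of 4.51.

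Cd36 was lower in the CD36KO pool at each of its 3 probe sets. The probe set used for the gene read 7.68 in WT and 6.02 in CD36KO, a 3.17-fold lower value. A further one read 7.70 and 5.87, 3.56-fold lower, and the last read 4.74 and 3.52, 2.33-fold lower. In CD36KO the last reading alone was below the filter. The position of the probe sets relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part would not check the labels. Of the 20 protein-coding genes nearest to Cd36 on chromosome 5, 7 were above the filter and 2 of them differed by at least 1.5-fold, Sema3c (1.96-fold higher, with another probe set at 0.08) and Phtf2 (1.52-fold higher, with another probe set at -0.42). The fixed list of 33 genes near Cd36 had a median difference of 0.13 over 17 members, inside the range of random lists; Pus7 (1.78-fold) and Armc10 (1.53-fold) were the other members at least 1.5-fold higher.

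Among the 11981 genes above the filter, 193 were at least 2-fold higher and 75 at least 2-fold lower in the CD36KO pool. At 1.5-fold these counts were 636 and 396, and 91.4% of the genes lay within 1.5-fold. The highest differences were those of Pla2g4c (113-fold, a cytosolic phospholipase A2), Fabp6 (102-fold, the ileal bile acid binding protein), Saa1 (94.1-fold, an acute-phase serum amyloid), Retnlb (39.4-fold, a goblet cell peptide), Gsdmc2 (34.4-fold, a gasdermin), Mgat4c (24.4-fold), Fgf15 (17.2-fold, the ileal hormone that represses bile acid synthesis in the liver), Plb1 (16.1-fold) and Suox (14.7-fold, sulfite oxidase). Reg2 (13.7-fold), the gastrokines Gkn1 (13.3-fold) and Gkn2 (12.4-fold), Tmigd1 (11.8-fold), the monocarboxylate transporter Slc5a8 (10.4-fold) and an immunoglobulin kappa probe set, Igk (9.96-fold), completed the 15. The WT values of Pla2g4c, Saa1, Retnlb, Mgat4c and Fgf15 lay between 3.37 and 3.88, below the filter, so their folds depend on an unknown background. Of the 5 genes in this group with several probe sets, 3 were at least 1.5-fold higher at every one, but of very different size for Pla2g4c, at 6.82 and 1.18. The second probe set read 7.18 for Saa1 and 4.64 for Gkn1. Plb1 had a probe set at 0.14 and Igk one at -0.48.

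The lowest values relative to WT were those of Cyp1a1 (13.0-fold lower, a cytochrome P450 induced by the aryl hydrocarbon receptor), Gsta2 (5.74-fold, a glutathione transferase), Mid1 (5.11-fold), Rab30 (3.76-fold), Hsd17b13 (3.60-fold, a lipid droplet dehydrogenase), Ces2g (3.53-fold), Vwce (3.49-fold), Aqp8 (3.44-fold, a water channel), Ces2b (3.27-fold) and Acaa1b (3.21-fold, a peroxisomal thiolase). Cd36 itself, Slc37a2 (3.05-fold), Paqr9 (3.04-fold), Lars2 (2.97-fold) and Rsad2 (2.91-fold, an antiviral interferon-induced protein) followed. Another probe set read a difference of 0.03 for Mid1, 0.05 for Lars2, -0.24 for Rsad2, -0.32 for Hsd17b13, -0.41 for Paqr9 and -0.51 for Rab30. Of the 7 genes in this group with several probe sets, Cd36 alone was at least 1.5-fold lower at every one.

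**Figure D1:**
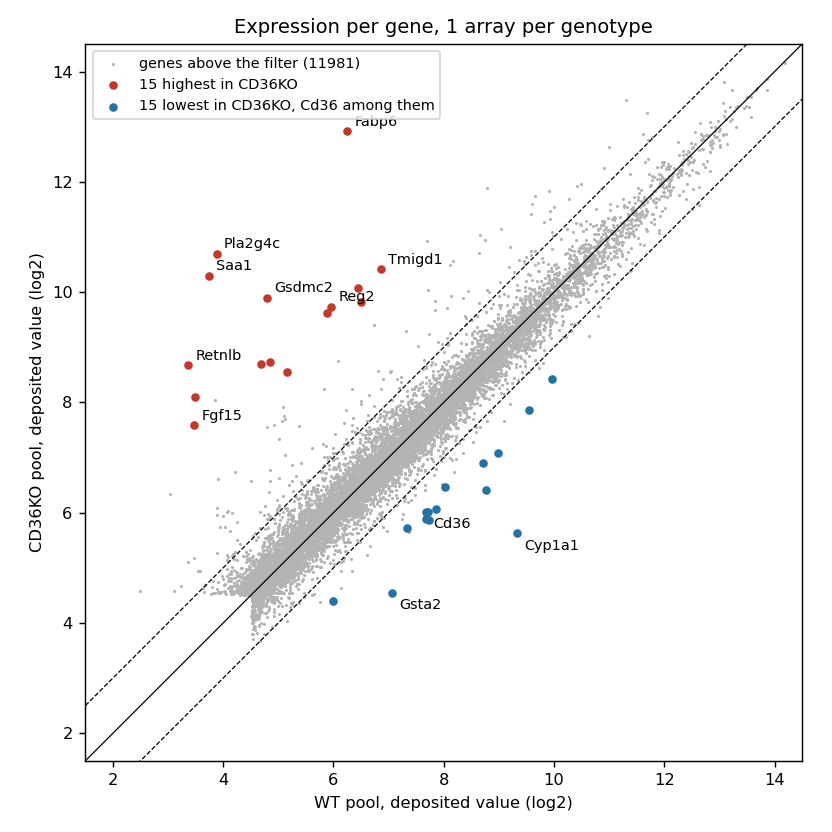
Deposited log2 value of each of the 11981 genes above the filter in the WT pool (x axis) and the CD36KO pool (y axis), with equality (solid line) and 2-fold differences (dashed lines). Red and blue points are the 15 genes with the largest difference in each direction; the red points range from 9.96-fold higher for Igk to 113-fold for Pla2g4c, and the blue from 2.91-fold lower for Rsad2 to 13.0-fold for Cyp1a1.

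Extracellular matrix genes were higher in the CD36KO pool. Of 54 members above the filter, 23 were at least 1.5-fold higher, 0 were at least 1.5-fold lower, and the median difference was 0.45 (1.37-fold), at percentile 100 of matched random lists, whose range was -0.09 to 0.08. The interstitial collagens had a median of 0.64 with 7 of 14 members higher, among them Col3a1 (2.24-fold), Col6a3 (2.17-fold) and Col1a1 (2.58-fold, but 0.06 at its second probe set). Fibronectin, Fn1, was 2.29-fold higher (0.51 at another probe set), and of the small proteoglycans that bind collagen Lum was 2.88-fold and Dcn 2.40-fold higher, the latter with -0.08 at another probe set. In this group of fibronectin, proteoglycan, elastic fibre and matricellular genes the median was 0.56 and 12 of 25 members were higher. The basement membrane genes differed less, with a median of 0.28 and 4 of 15 higher, including Col4a1 (1.87-fold) and Lama2 (1.51-fold). Lama3 (2.41-fold), Lama4 (1.71-fold) and Col1a2 (2.21-fold) each had a probe set with the opposite sign, at -0.15, -0.55 and -0.43. The median of all matrix genes was 0.25 with the probe set of smallest difference per gene, 0.29 without a filter and 0.77 with the 75th percentile filter. In the same pools the 3' bias of the control RNAs was lower in CD36KO, and the medians were 0.39 for smooth muscle markers, 1.32 for distal segment genes and 1.60 for pancreas genes.

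Enzymes that cut, inhibit or crosslink the matrix had a median of 0.39, and 6 of 25 members were at least 1.5-fold higher. Mmp7, a matrilysin made by Paneth cells, was 5.21-fold higher, Loxl1, a crosslinking oxidase, was higher by 0.85 (log2; 0.38 at another probe set), Timp3 1.71-fold (another probe set at -0.20) and Mmp2, a gelatinase, 1.70-fold. Integrin and focal adhesion genes had a median of 0.15, with Itga9 2.57-fold, Itgb1 2.11-fold (another probe set at -0.48), Fermt2 1.73-fold and Itgb6 1.63-fold higher, the 4 of 22 members past 1.5-fold. Other probe sets read 0.09 for Itga9, 0.05 for Fermt2 and 0.19 for Itgb6. Junction genes of the epithelium had a median of 0.20, and 1 of 27 members passed 1.5-fold, Cldn2 (2.25-fold higher), a claudin that forms a cation pore.

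Lists of gut wall markers had medians above 0, as the matrix genes did. Smooth muscle and pericyte markers had a median of 0.39, with 5 of 20 higher, among them Myl9 (1.88-fold), Tagln (1.79-fold), Actg2 (1.79-fold) and Myh11 (1.74-fold, 0.14 at another probe set). Fibroblast and interstitial cell of Cajal markers had a median of 0.63 with 7 of 14 higher, including Adamdec1 (2.04-fold), F3 (1.88-fold) and Cd34 (1.76-fold). Blood endothelial markers had a median of 0.35 with 4 of 21 higher, Emcn (1.78-fold) and Pecam1 (1.78-fold) among them. The lymphatic endothelial list had a median of 0.26, with 3 of 8 members higher, Itga9, Vegfc (2.21-fold) and Lyve1 (1.58-fold), and -0.035 with the mean over probe sets. Other probe sets read 0.00 for Vegfc and 0.13 for Lyve1. Enteric neuron and glia markers had a median of 0.21, inside the range of random lists, with Gal (2.08-fold higher) the 1 of 12 past 1.5-fold.

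Neutrophil markers were mostly below the expression filter in both pools. Of 23 measured, 17 were below the filter, and the 6 above it had a median difference of 0.02, at percentile 48.6 of random lists, and this median was -0.0098 under quantile normalization. Cd177 was 4.16-fold higher, from 4.51 in WT to 6.57 in CD36KO. Its WT value was just under the filter, which it passed through CD36KO alone. The other members above the filter, Il1r2, Hdc, Ltf, Mmp9 and Elane (neutrophil elastase), differed by between -0.25 and 0.25. S100a8 and S100a9, calprotectin subunits abundant in neutrophils and named after their values were seen, read 3.45 and 3.19 in WT and 3.38 and 3.19 in CD36KO. A difference in the markers below the filter was not detectable at this signal. Chemokines that recruit neutrophils and acute cytokines had a median of 0.06. Saa1, Saa2 (3.86-fold) and Saa3 (1.58-fold) were higher, Csf2 was 1.69-fold lower, and 9 of the 13 members lay within 1.5-fold.

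Other immune lists differed in size. In the same pools fibroblast markers had a median of 0.63 and blood endothelial markers one of 0.35, and the 3' bias of the control RNAs was lower in CD36KO. Macrophage and dendritic cell markers had a median of 0.24 with 4 of 17 higher, Cd68 (3.28-fold, from a WT value of 3.46), Lyz2 (2.16-fold) and the complement genes C1qc (1.77-fold) and C1qa (1.74-fold). B and plasma cell markers had a median of 0.25 with 2 of 18 higher, Ms4a1 (1.94-fold, 0.53 at another probe set) and Pou2af1 (1.91-fold). Of 15 mast cell and eosinophil markers measured, 4 were above the filter and higher, Mcpt1 (3.88-fold, from 4.06 in WT, under the filter), Mcpt2 (2.06-fold), Siglecf (1.91-fold) and Kit (1.75-fold, with another probe set at -0.01). Kit also belongs to the interstitial cell of Cajal list, and the members below the filter differed in both directions, as Tpsb2 (-0.52) and Prg2 (0.49). The median of the mast cell list was 0.99, and 0.21 without the filter. MHC and antigen presentation genes had a median of 0.22 with 1 of 17 past 1.5-fold, H2-T3 (3.99-fold, 0.69 at another probe set). H2-DMa (1.43-fold, -0.30 at another probe set) and Cd74 (1.39-fold) followed. T and NK cell markers had a median of -0.08, inside the range of random lists, with 1 of 16 past 1.5-fold, Klrd1 (1.85-fold lower). Interferon response genes had a median of 0.05, with 4 of 35 higher (Ifit2 2.20-fold, Iigp1 2.22-fold, the latter 0.32 at another probe set) and 2 lower (Rsad2 and Ifit3, the latter 1.63-fold).

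**Figure D2:**
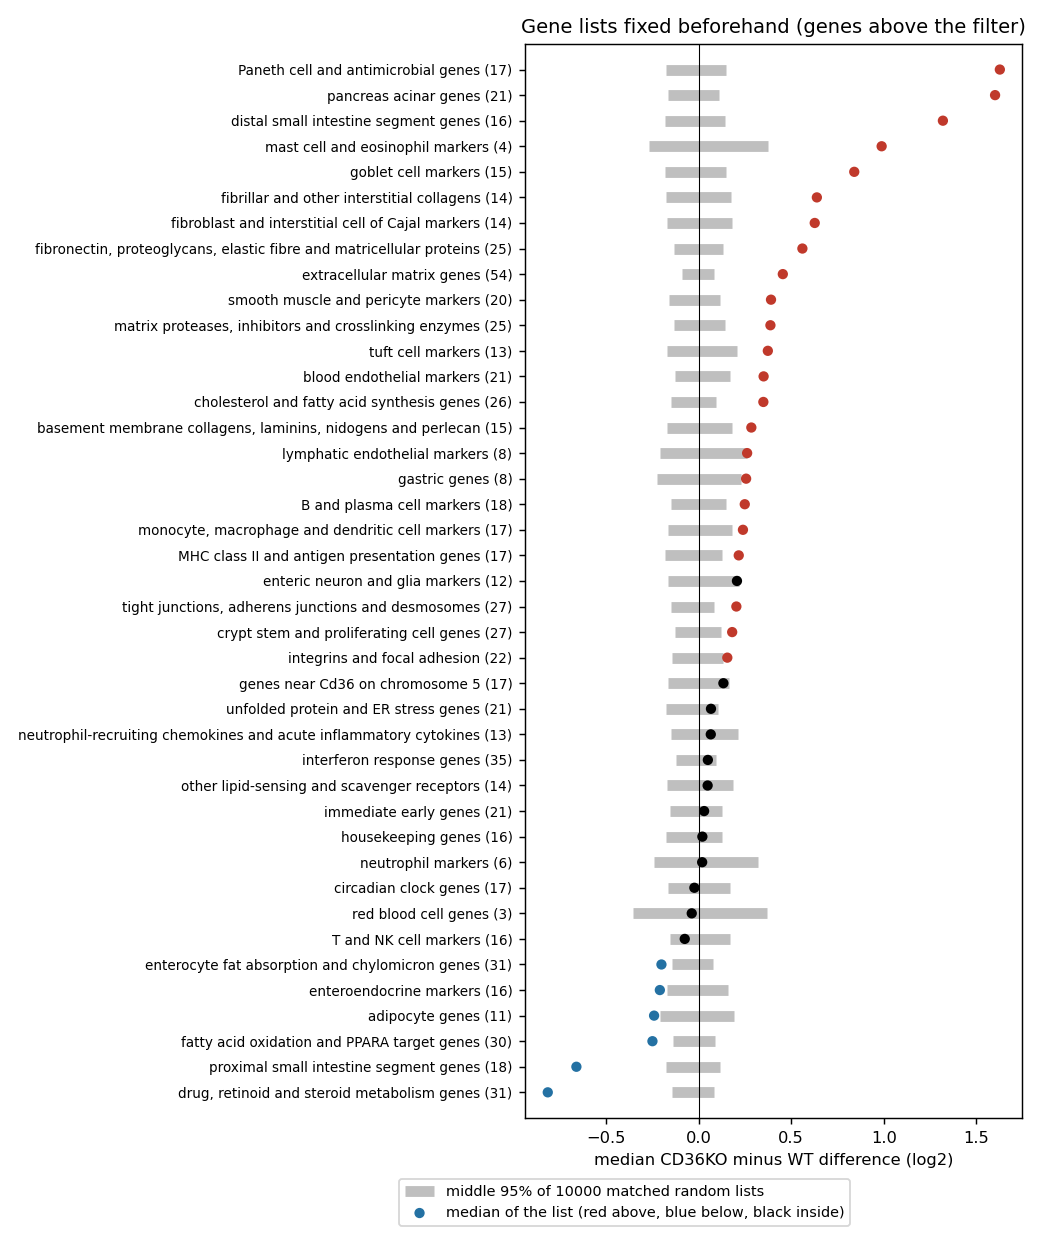
Median CD36KO minus WT difference (log2, x axis) of the members above the filter, whose number is in parentheses, for each list of at least 3 genes (points), with the middle 95% of 10000 random lists matched on expression (grey bars). Of the 41 lists shown, 23 lie above the bar, 6 below and 12 inside. They leave out Y-linked genes and Xist and include the joined extracellular matrix list beside its 3 parts, all above. Neutrophil markers are inside at 0.02 and extracellular matrix genes above at 0.45.

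Genes that mark position along the small intestine differed in opposite directions. Of 16 genes of the distal small intestine, 12 were at least 1.5-fold higher in the CD36KO pool and 0 lower, with a median of 1.32, led by Fabp6, Fgf15, Tmigd1 and Guca2a (4.24-fold). Slc10a2, the ileal bile acid transporter, was below the filter in WT and read 4.58 in CD36KO. Of 18 genes of the proximal small intestine, 10 were at least 1.5-fold lower and 0 higher, with a median of -0.66 (1.58-fold lower). These included the duodenal transcription factor Pdx1 (2.40-fold, though level at its second probe set), the calcium channel Trpv6 (2.23-fold), the iron exporter Slc40a1 (2.14-fold, -0.53 at another probe set) and the carboxylesterase Ces1f (2.13-fold). Enteroendocrine genes differed in both directions: Pyy (2.93-fold), Gcg (2.07-fold) and Nts (1.93-fold) were higher, Neurog3 was 1.62-fold lower (-0.05 at another probe set), and the list had a median of -0.21 and a mean of 0.02. Pyy and Nts belong to the distal list as well.

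Genes of tissue next to the small intestine differed too. Of 21 pancreas acinar genes, 19 were at least 1.5-fold higher in CD36KO and the median was 1.60 (3.04-fold). Reg2, Prss3 (9.86-fold, from 3.03 in WT, under the filter), Pnliprp2 (8.61-fold) and Cpa1 (5.29-fold) were highest. Of 8 gastric genes, Gkn1, Gkn2 and Tff1 (4.55-fold) were higher, while Gkn3 was 1.69-fold and Tff2 1.62-fold lower, with a median of 0.26 and a mean of 1.01. Adipocyte genes had a median of -0.24 and 2 of 11 were lower, Pparg 2.25-fold and Thrsp 1.56-fold, the latter with 0.07 at another probe set. Red blood cell genes had a median of -0.04 over 3 members.

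**Figure D3:**
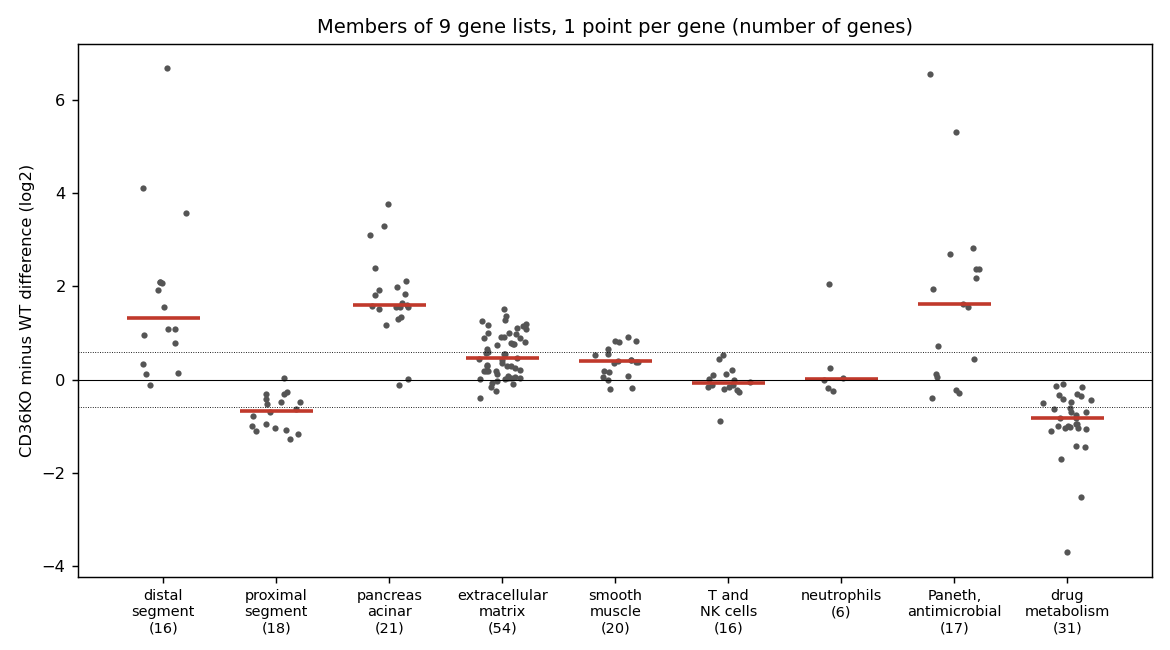
CD36KO minus WT difference (log2, y axis) of each gene above the filter in 9 of the lists (points, number of genes in parentheses), with the median of the list (red line), 0 (solid line) and 1.5-fold (dotted lines). Distal segment and proximal segment genes lie on opposite sides of 0, at medians of 1.32 and -0.66, and 19 of 21 pancreas genes lie above the upper dotted line.

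Genes of the Paneth and antimicrobial list and of the goblet list were mostly higher, as were the distal segment genes, of which the goblet list holds 1. Paneth cell and antimicrobial genes had a median of 1.63 (3.09-fold) and 11 of 17 were higher, Saa1, Retnlb, Pla2g2a (7.08-fold, a bactericidal phospholipase) and Duoxa2 (6.49-fold, the partner of an epithelial oxidase) most. Members that did not pass 1.5-fold included the defensin Defa31 (0.12), Reg1 (-0.40) and Reg3a (-0.28). The Paneth product Lyz1 was 1.36-fold higher, with another probe set at 1.07. Goblet cell markers had a median of 0.84 and 9 of 15 were higher, including Clca1 (2.37-fold), Ccl6 (2.25-fold), Agr2 (2.20-fold) and the mucin Muc2 (2.08-fold). Tuft cell markers had a median of 0.37 with 10 of 13 within 1.5-fold and 3 higher, Siglecf, Cd24a (1.67-fold, 0.19 at another probe set) and Avil (1.54-fold). Crypt stem and proliferation genes had a median of 0.18 with 2 of 27 higher, Aurkb (1.93-fold, 0.40 at another probe set) and Lgr5 (1.82-fold, -0.10 at another probe set).

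Lipid genes differed in direction by pathway. Of 31 genes of fat absorption and chylomicron assembly, Apob, the structural protein of the chylomicron, was 2.71-fold lower (-0.45 at another probe set), Scarb1 was 1.45-fold lower, and the median was -0.20. Cel (3.50-fold) and Clps (2.93-fold) were higher and are pancreas genes also held by the acinar list. The fat absorption list shares 2 members, Fabp1 (-0.41) and Slc27a4 (-0.26), with the proximal segment list, and that list's median was -0.66. Fatty acid oxidation and PPARA target genes had a median of -0.25, lower like the proximal segment genes, with 6 of 30 lower and 0 higher, among them Acaa1b, Pdk4 (2.02-fold), Acot1 (1.88-fold) and Acot12 (1.67-fold, with 0.44 at another probe set). Cholesterol and fatty acid synthesis genes had a median of 0.35, with 7 of 26 higher, led by Sqle (3.95-fold), Scd2 (3.55-fold, with other probe sets from 0.65 to 2.86), Fdps (2.22-fold, -0.06 at another probe set) and Msmo1 (2.04-fold, -0.21 at another probe set). The cholesterol list's median was 0.15 with the probe set of smallest difference per gene, and in the same pools the distal segment median was 1.32 and the 3' bias of the control RNAs was lower in CD36KO. Other lipid-sensing and scavenger receptors had a median of 0.05 with 10 of 14 within 1.5-fold, Cd68, Ffar4 (2.11-fold) and Tlr2 (1.74-fold) higher and Slc27a2 1.78-fold lower.

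Drug, retinoid and steroid metabolism genes were lower in CD36KO, as were the proximal segment genes, with 21 of 31 at least 1.5-fold lower, 0 higher and a median of -0.82 (1.76-fold lower). Besides Cyp1a1, Gsta2 and Ces2b, the exporter Abcc2 was 2.72-fold lower. Lists chosen to mark handling, time of day and scaling had medians near 0. These were 0.03 for immediate early genes, -0.02 for circadian clock genes and 0.02 for housekeeping genes, with 0 of 16 past 1.5-fold. Of 17 clock genes 8 were higher and 9 lower, and 1 passed 1.5-fold, Npas2 (1.56-fold lower, -0.32 at another probe set). A shift raising some clock genes and lowering others would leave this median near 0, so it does not exclude 1. The housekeeping median does not check the scaling, as both array medians were 4.38 already. Hybridization (-0.28) and poly-A controls (-0.57) were lower in CD36KO. Unfolded protein and ER stress genes had a median of 0.07 with 18 of 21 within 1.5-fold, Asns (1.72-fold, 0.48 at another probe set), Pdia6 (1.66-fold, 0.44 at another probe set) and Sdf2l1 (1.53-fold) higher.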

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

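All results rest on 1 array per genotype, and no alternative can replace the missing replicates. Low values lacked a background measure, which limits folds against readings under the filter. Named genes under the filter in WT included Prss3 (3.03), Pecam1 (3.90), Duoxa2 (3.91), Saa2 (3.99), F3 (4.08), Vegfc (4.08) and Ffar4 (4.21). The 2-fold counts of 193 higher and 75 lower genes became 636 and 396 at 1.5-fold and 71 and 14 at 3-fold. With the probe set of smallest absolute difference the lower count was 47; under the other alternatives both stayed within 1.5 times. The difference of Cd36 was -1.65 after centring, -1.69 after quantile normalization, -1.57 as the mean of its probe sets and -1.22 at the one of smallest difference. The matrix median of 0.45 was 0.47 after centring, 0.44 after quantile normalization, 0.47 after the lowess step, 0.56 with mean probe sets, 0.25 with that of smallest difference, 0.29 without a filter and 0.77 at the 75th percentile. The neutrophil median of 0.02 was 0.031 after centring, -0.0098 after quantile normalization, -0.0094 with mean probe sets, -0.0075 with that of smallest difference and 0.012 without a filter; at the 75th percentile 0 members were left. Of the 131 named genes past 1.5-fold, 129 stayed past it under quantile normalization and 111 with the mean over probe sets. Of the 28 lists outside the random range, other than the joined matrix list, the mean over probe sets reversed 1, lymphatic endothelial markers, to -0.035. The median was under 2/3 of its reported size in 11 lists with the probe set of smallest difference, in 6 without the filter, in 3 with mean probe sets and in 3 of 27 at the 75th percentile. The probe set of smallest difference reversed 13 named genes: Acot12 (0.44), Col1a2 (-0.43), Dcn (-0.081), Fdps (-0.060), Kit (-0.0064), Lama3 (-0.15), Lama4 (-0.55), Lars2 (0.0074), Lgr5 (-0.095), Mid1 (0.030), Msmo1 (-0.21), Phtf2 (-0.42) and Timp3 (-0.20); this choice by construction favours the smallest difference, and 89 of the 131 genes stayed past 1.5-fold. The cause of these disagreements between probe sets was not tested.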

Other observations

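The tests of the bile acid, epithelial share, gut wall and 3' bias explanations were chosen after their values had been seen, and those of the further segment genes and the further pancreas genes were set before. Several of the highest genes in the CD36KO pool belong to a group that intestinal type 2 immune responses are known to raise, a list written after the extremes had been seen and therefore not independent of them. Of 15 members above the filter, 9 were at least 1.5-fold higher and the median difference was 1.25 (2.37-fold): Pla2g4c, Retnlb, Gsdmc2, Mptx1 (7.70 in WT, 10.93 in CD36KO), Ang4 (another probe set at 3.48), Mcpt1, Itln1, Clca1 and Mcpt2. Retnlb, Ang4 and Itln1 also belong to the Paneth list, Clca1 to the goblet list, and Mcpt1 and Mcpt2 to the mast cell list. The Paneth and goblet lists were higher together with the distal segment genes, so this group is not separate from those patterns. Pla2g4c (3.88), Retnlb (3.37) and Mcpt1 (4.06) were under the filter in WT and passed it through CD36KO alone. Ccl24 was lower, at 6.87 in WT and 6.01 in CD36KO. The cytokines Il4, Il5, Il13 and Il25 were all below the filter in both pools, and Il33 read 7.54 and 7.67. Among probe sets without a single gene name, 40 above the filter were at least 2-fold higher and 35 at least 2-fold lower in CD36KO.

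The first pattern is the opposite shift of distal and proximal segment genes. Raised bile acid receptor activity was examined by leaving Fabp6, Fgf15, Slc51a, Slc51b and Slc10a2, grouped here as receptor targets, out of the distal list. The remaining 11 genes still had a median of 0.95, and the proximal list, at -0.66, lay below its random range. These values argue against activity that raised only the genes left out. The test was written after the values had been seen, so it is no independent check. The direction in which the receptor regulates each gene was not examined. A candidate explanation is that the CD36KO pool held more distal gut than the WT pool: the median of 8 further distal genes exceeded that of 13 further proximal genes by 0.63, past the bound of 0.3 set beforehand. That difference came from the proximal side, at -0.54, since the further distal genes were at 0.08, inside their random range. In the same pool 19 of 21 pancreas acinar genes and the gastric genes Gkn1, Gkn2 and Tff1 were higher, while Gkn3 and Tff2 were lower. More distal gut alone does not account for the higher pancreas and gastric genes. An effect of genotype on regional identity or on the balance of enterocytes and secretory cells stays open, as it was not tested.

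The second pattern is the higher level of extracellular matrix genes. More gut wall in the CD36KO pool is a candidate explanation. The 34 smooth muscle and fibroblast markers that are not matrix genes had a median of 0.47, close to the matrix median. They join lists already seen above their random ranges, at 0.39 and 0.63, so their median is no independent check. Enteric neuron and glia markers, also of the gut wall, were at 0.21, inside their random range. The more 3' biased RNA of the WT pool stays open. Over the 24 matrix genes with several probe sets the median was 0.31. It was 0.14 at the probe set of smallest difference, with a random range of -0.06 to 0.06. That choice favours small differences by construction, so the drop does not speak for 3' bias. How far each probe set lies from the 3' end is not known here. Epithelial lists lay on both sides of 0, so the test of a smaller share of epithelium alone was split. Junction (0.20), goblet (0.84), Paneth (1.63), tuft (0.37) and crypt genes (0.18) lay above their random ranges. For the genes of these lists the values argue against a smaller share alone. Fat absorption genes without pancreas members (-0.21), drug metabolism genes (-0.82) and enteroendocrine genes (-0.21, with a mean of 0.02) lay below theirs. A smaller share together with other changes stays open. Macrophage, B cell and blood endothelial markers had medians of 0.24, 0.25 and 0.35. Of these, 4 of 17, 2 of 18 and 4 of 21 were at least 1.5-fold higher. T and NK cell markers, many of them of lymphocytes within the epithelium, were at -0.076. A higher level of matrix genes within stromal cells and a larger amount of stroma, from dissection, gut segment or genotype, stay open.

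The third pattern is the higher level of 19 of 21 pancreas acinar genes. More pancreas attached to the CD36KO tissue is a candidate explanation: 10 further pancreas genes above the filter had a median of 0.45, past the bound of 0.3 set beforehand, with Klk1 at 0.93 (0.16 at another probe set) and Cuzd1 at 0.78. Of these 10 genes 3 were at least 1.5-fold higher, and their median was well under the 1.60 of the acinar list. Abundant members of the acinar list itself were higher, Pnliprp2 with 8.79 in WT and 11.89 in CD36KO and Clps with 9.93 and 11.48. As members of the list to be explained they are no further support. Of the 21, the fat absorption list holds 2 and the goblet list 1. Of the islet hormones, Ins2 was at 0.45 and Iapp at -0.51, with another probe set at 0.18. No biological explanation was tested for this pattern, and an effect of genotype on these genes stays open.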
